A study of Drosophila melanogaster with 2 samples.

How the data were processed

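The samples were 2 biological replicates of anti-GFP ChIP-seq from whole pupae (pooled sexes, labelled 24 hours) of a line carrying CG1663 fused to GFP. Per the labels, chromatin was fragmented by sonication and the size range was 200 to 800. Per the README deposited with each sample, peaks were called for replicate 1, for replicate 3 and for the pooled alignments, each against the same single control file, on assembly dm6, and an optimal IDR-thresholded list was derived from these 3 lists. The peak caller, the IDR program, their versions and the IDR threshold are not given in the sources used here, nor are the aligner, the filters on reads and the treatment of reads that match several places.

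The deposited lists are in narrowPeak format. The authors' signal of each peak (column 7) is the caller's own value relative to the control, never negative and not whole, and it is comparable within a list only. The deposited q-value column (column 9) holds −log10 of the q-value, as the format defines it, and is saturated: 10123 peaks of replicate 1, 13534 of replicate 3 and all 9657 IDR-thresholded peaks share the highest value of their list. Peaks were therefore ranked by signal. The authors' column 10 gives the summit as a distance from the peak start, and it was used as given, although in up to 10 peaks of a list it lay at or past the peak end. The lowest signals were 17.2 in replicate 1, 14.5 in replicate 3 and 170.2 in the IDR-thresholded list. Each of the 3 called lists held exactly 30000 peaks, so their sizes were set by a limit on number. The IDR-thresholded list was tested against the pooled list, and it held exactly the 9657 pooled peaks with the highest signal, of which 307 overlapped no replicate 1 peak and 202 no replicate 3 peak. Peak lists give no read totals, so the depth is unknown, and the precision of each share comes from the number of peaks or genes behind it.

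The genome was Release 6 (dm6) and gene models came from Ensembl release 115 (BDGP6.54). Every peak end lay inside its reference arm, and 17413 of 17415 genes shared with the RefSeq annotation had the same coordinates. The arms X, 2L, 2R, 3L, 3R and 4 held 18164 genes, of which 13945 were protein-coding. Positions were counted from 1. Each summit was given to 1 class in the order promoter (within 500 bp of any annotated transcript start), 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic, and the same was done for 96570 random positions on the same arms.

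Replicates were compared on their 9657 strongest peaks, with an overlap of at least 1 bp, 100 shuffles by bedtools and the Spearman correlation of signals. A gene was bound when a summit lay within 500 bp of any of its starts. The 35 gene lists, of housekeeping groups, complexes, pathways, tissue markers and classes that ChIP often enriches, were tested by two-sided Fisher exact tests against all other genes. Of the members written into the lists, 2269 were matched to a gene and 9 were not. Odds ratios have Wald intervals, with a correction where a count was 0. The 22 motifs, written as consensus sequences, were searched on both strands within 50 bp of each summit. Control windows, 1 for each summit, lay at the same signed distance from a start of a random gene without an IDR-thresholded peak within 1000 bp. Words of 8 bases were ranked on 2L, 3L and X and the top 10 tested on 2R, 3R and 4. P-values were adjusted by Benjamini and Hochberg within each family, with a threshold of 0.05. Genes bound in 1 replicate alone were compared by exact McNemar tests. Shares have exact (Clopper-Pearson) 95% intervals, and a count of 0 was given the limit of 3 counts.

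Named genes followed a rule fixed before the data were examined: CG1663, the genes nearest to the 25 peaks with the highest signal, up to 4 bound members with the highest signal of each list with more bound genes and up to 3 of each list with fewer, and the 3 peaks in each direction whose rank differed most between the replicates. The tests, lists, motifs, window sizes and the alternatives below were fixed before the data were examined too, unless stated otherwise.

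The alternatives were the 50% of peaks with the stronger signal, the strongest 9657 pooled peaks, each replicate list alone, promoter windows of 200 and 1000 bp, protein-coding genes only, any base of the peak in place of the summit, expected arm shares from starts, 10000 circular shifts of the bound calls along the gene order, windows of 100 bp to each side, flanking control windows 1000 bp away, words of 6 bases, exchanged arms, and other overlap rules (50% of both peaks, summits within 100 bp, all peaks, the top 1000). Chosen after seeing the data were GC-matched control windows (drawn from anywhere on the arms, clear of peaks and not matched in distance to a start), 1 summit per merged region, Mantel-Haenszel tests over strata of the number of starts of a gene, and Fisher exact tests of the genes bound in 1 replicate alone against the other genes. All peaks of the 4 lists lay on the 6 arms, and none was left out. The control was not analysed here.

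The programs were Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and bedtools 2.31.1. The steps were tested on simulated data before use. With 18164 simulated genes, a true odds ratio of 6 for the ribosomal protein list gave a median estimate of 6.12 and was called in 50 of 50 runs, and a true 0.3 for transfer RNA genes gave 0.282 and was called in 50 of 50 runs. Lists without an effect were called 3 times in 1650 tests. Bound calls were simulated for each gene on its own, whereas a real summit can count for several neighbouring genes, so the real rate may differ. A Mantel-Haenszel odds ratio of 3 was estimated as 3.09. A motif put into 3% of 4000 windows was called in 10 of 10 runs, motifs without an effect in 0 of 60 tests, and its words passed on the other arm in 10 of 10 runs. Both sets of simulated windows had the same base composition, whereas real summit and distance-matched control windows held 31.7% and 42.5% G and C. These runs therefore give no rate of false calls for the motif and word tests on the real windows. Classes of 900 positions matched a plain search in all 900, and overlap counts equalled those of bedtools.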

Results

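Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the product of CG1663, which the labels treat as a transcription factor, sat on the genome of Drosophila melanogaster. The material was whole pupae labelled 24 hours, with males and females pooled, from a transgenic line in which GFP was fused to the C terminus of CG1663, and an antibody to GFP was used for the precipitation. There was 1 group with 2 biological replicates, numbered 1 and 3, and no second condition, so the comparisons are between the replicates and between bound sites and the rest of the genome. The deposited lists from replicate 1, replicate 3 and both pooled held 30000 peaks each. The list thresholded by the irreproducible discovery rate (IDR), a measure of how alike 2 replicates rank their peaks, held 9657 peaks. Peak lists give no read counts, so the depth of each library is unknown. No untagged line was analysed here. Positions are on build dm6 (Release 6), counted from 1.

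The replicates placed most of their stronger peaks at the same sites. Of the 9657 peaks with the highest signal in each list, 79.2% of those of replicate 1 (7652 peaks, 95% exact interval 78.4 to 80.0) overlapped one of replicate 3, and 81.3% of those of replicate 3 (7851 peaks, 80.5 to 82.1) overlapped one of replicate 1. Peaks shuffled within their chromosome arms 100 times overlapped in 4.74% and 4.85% of cases on average, with highest values of 5.36% and 5.33%. Among the 1000 strongest peaks of each list the shares were 90.4% and 90.3%. Across the 9153 IDR-thresholded peaks with a match in both replicates, the Spearman correlation of the deposited signal was 0.880. No value for chance was computed for this correlation, as both replicates were called against the same control, peaks were kept for having a match in both, and the lists hold no reads from which the share due to this could be measured. The overlap above has the same limit as to the control. Peaks and genes are not independent replicates, and the intervals here and below cover counting error only.

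The strongest site of the IDR-thresholded list lay 90 bp upstream of CG14100 on chromosome 3L (19590361 to 19590875, intergenic), with a signal of 10165.7, and ranked 1 in replicate 1 and 3 in replicate 3. It was followed by a site in an intron of CG11050 on 2L (6612349 to 6613051, signal 9868.65) and by a site on 2L (480304 to 481392, signal 9389.41) in an intron of ush, which encodes a cofactor of GATA factors. The start nearest to the latter was that of cbt, a Krüppel-like transcription factor, 1398 bp away. A pair of the 25 strongest peaks flanked the start of lncRNA:CR44619 on X, 537 bp upstream in an exon of lncRNA:Vinr (12750711 to 12751740, signal 9107.34) and 508 bp downstream in an exon of lncRNA:CR44619 (12751923 to 12752638, signal 6254.65). Next came the promoter of Ugalt, a UDP-galactose transporter, on X (2703631 to 2704153, signal 8479.52), with its summit 32 bp upstream of the start.

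Of these 25 peaks, 14 had their summit within 500 bp of an annotated start, 6 lay in introns, 3 in exons of noncoding RNAs and 2 between genes. The promoters included those of larp (an RNA-binding protein), mRpL41 (a mitochondrial ribosomal protein), CG18549, PNPase, Art3, Fkbp14, Chro (a chromatin protein of the spindle and of interbands), lncRNA:CR31044, CG18428, Tcs5, gish and the small heat shock gene Hsp27. Summits in introns or noncoding exons lay nearest to the starts of CG32772, HmgZ, Lk6, CG4496 and lncRNA:CR46035, and the intergenic ones nearest to CG13323, 11911 bp away, and CG31668, 3760 bp away. Signals ranged from 6207.74 at Hsp27 to 10165.7 at CG14100. No peak of this set ranked below 29 in replicate 1 or below 32 in replicate 3.

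At some sites the replicates ranked the signal differently. The IDR-thresholded peak 113 bp upstream of HP4, a gene for a heterochromatin protein, on 3L (7976078 to 7976459) ranked 2461 in replicate 3 with a signal of 303.375 and 18791 in replicate 1 with 35.9695. In the other direction, the peak 74 bp upstream of Pgant1, a glycosyltransferase gene, on 2R (15511439 to 15511783) ranked 2890 in replicate 1 and 23047 in replicate 3. The intergenic peak nearest to CG43131 on 3R (5112361 to 5112759) ranked 2424 in replicate 1 and 15728 in replicate 3. At HP4 the matched replicate 1 summit lay 177 bp away and at Pgant1 the matched replicate 3 summit 206 bp away. The other 3 peaks singled out by rank came from the matching, since the stronger replicate peak given to each also matched a neighbouring site that was closer to its summit. These were a peak near CG31668 on 2L (2203275 to 2203615, signal 211.161), matched to a replicate 3 peak of signal 3124.36 that belonged to the site of rank 12, a peak in the 5' UTR of Mtpalpha on 2L (9576558 to 9576769, signal 309.082), whose replicate 3 match of signal 477.708 belonged to the site of rank 2377, and a peak in an intron of CG18507 on 2L (13666483 to 13666708, signal 237.91), whose replicate 1 match of signal 423.904 belonged to the site of rank 2945.

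CG1663 itself (FBgn0033449, 2R, 9836985 to 9838481, plus strand) had no IDR-thresholded summit within 500 bp of its start. The nearest one lay 1797 bp upstream, outside the gene, with a signal of 244.738 and rank 7225. Replicate 3 alone held a summit 43 bp upstream of the start of CG1663, with a signal of 26.9819 and rank 21665 of its list, and replicate 1 held none within 500 bp.

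Bound sites gathered at promoters and left coding exons almost empty. A summit within 500 bp of an annotated transcription start was found for 30.5% of the 9657 IDR-thresholded peaks (2946 peaks, 95% exact interval 29.6 to 31.4), against 13.7% of random positions on the same arms (13.4 to 13.9). The replicate lists gave 26.6% and 38.2%, with a mean of 32.4% ± 8.17 (SD, n = 2), and both lay above the random share. Coding exons outside promoters held 0.186% of summits (18 peaks, 0.111 to 0.294) against 13.1% of random positions, with 0.135% and 0.186% in the replicate lists, and 3' UTRs held 0.704% against 5.08%. Introns held 45.3% of summits (44.3 to 46.3) against 39.2% of random positions, and intergenic sequence held 21.6% (20.8 to 22.4) against 27.4%. Windows without a peak that were matched to the summits in GC content, an alternative chosen after seeing the data, lay in introns in 44.1% of cases (43.1 to 45.1). For introns the mean of the replicate lists was 44.2% ± 4.17 (SD, n = 2), and replicate 3 with 41.3% was the closer to the random share. For 5' UTRs the shares were 0.549% and 0.746%, and for exons of noncoding transcripts 1.23% and 0.799%. With a window of 200 bp the promoter share was 18.7%.

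**Figure D1:**
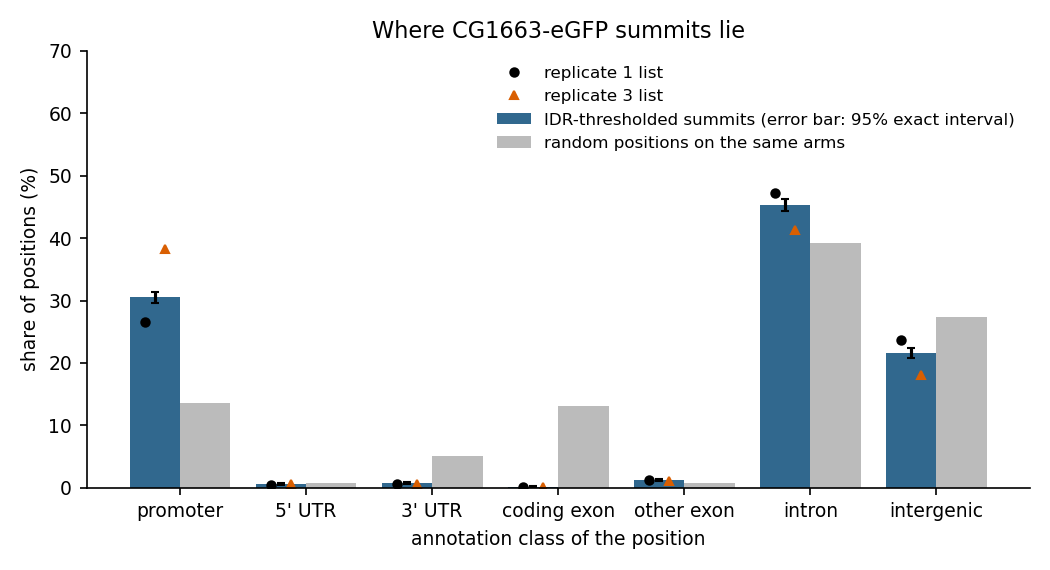
Share of positions in percent, by annotation class of the position, for IDR-thresholded summits (blue bars, with 95% exact intervals), random positions on the same arms (grey bars), the replicate 1 list (points) and the replicate 3 list (triangles). Promoters held 30.5% of summits against 13.7% of random positions, and coding exons 0.186% against 13.1%.

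Promoter summits sat on the upstream side of the start. Of the 2946 promoter summits, 75.9% (95% exact interval 74.3 to 77.4) were upstream, against 45.6% of random promoter positions (44.7 to 46.4), and the median position was −127 bp. The replicate lists gave 79.5% with a median of −151 bp and 70.2% with a median of −91 bp. Summits from 50 to 200 bp upstream made up 37.8% of promoter summits and 15.8% of random promoter positions.

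**Figure D2:**
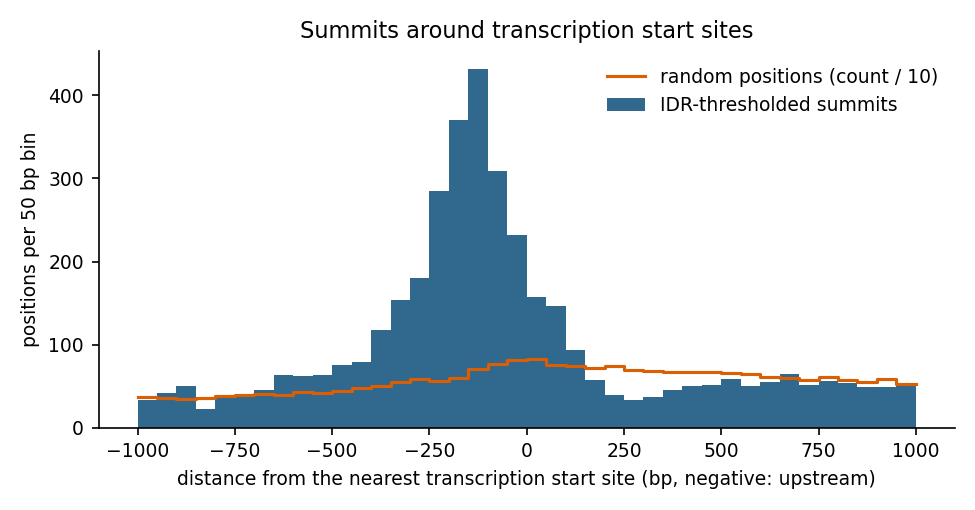
Number of IDR-thresholded summits and, scaled to the same number of positions, of random positions, by distance in bp from the nearest transcription start, with upstream distances negative. The summits pile up upstream of the start, with a median of −127 bp among those within 500 bp.

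Among the chromosome arms, chromosome 4, a small and largely heterochromatic chromosome, stood apart. It held 11 of the 9657 peaks, 0.114% (95% exact interval 0.0569 to 0.204) against 1.01% of the length of the 6 arms, a ratio of 0.113. The list of replicate 3 alone gave 24 peaks and a ratio of 0.247, more than the list of replicate 1 with 10 peaks and 0.103, and both were below 1. The other ratios lay between 0.889 for 2R and 1.09 for X, with 1.09 for 3L, 1.06 for 2L and 0.940 for 3R. The X chromosome held 19.2% of the peaks (1854 peaks) against 17.6% of the length, and 19.2% and 18.9% in the replicate lists.

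A gene was counted as bound when an IDR-thresholded summit lay within 500 bp of any of its annotated starts, so a summit between neighbouring starts counted for each of them. By this measure 3422 of 18164 genes were bound, 18.8% (95% exact interval 18.3 to 19.4), among them 2995 of 13945 protein-coding genes (21.5%) and 380 of 3261 genes annotated as ncRNA (11.7%). Replicate 1 gave 2998 bound genes and replicate 3 gave 4191, with 2682 in both, 316 in replicate 1 alone and 1509 in replicate 3 alone. Genes with more annotated starts were bound more often, from 13.9% of 14328 genes with 1 start to 30.8% of 2678 genes with 2 starts and 47.1% of 713 genes with 3 starts.

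Of 35 gene lists fixed before the data were examined, 10 held more bound genes than the rest of the genome and 7 held fewer (two-sided Fisher exact test, adjusted p below 0.05 over the 35 lists). Of the 12 glycolysis genes 9 were bound, 75.0% (95% exact interval 42.8 to 94.5) against 18.8% of other genes, an odds ratio of 12.96 (3.51 to 47.9, adjusted p = 1.5e-04), and each replicate list gave 8, with odds ratios of 10.1 and 6.68. The glycolytic genes with the highest signal were Gapdh2 (5203.35, summit 162 bp upstream, X, 15867740 to 15868254), Eno (4209.55), Hex-A (3522.45) and Ldh (1635.02). The estimate fell to 4.86 (Mantel-Haenszel chi-square, adjusted p = 0.0297) when genes were compared within strata of the number of starts, an alternative chosen after seeing the data.

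The cytoplasmic ribosomal proteins, which build the ribosome, had 59 of 92 genes bound, 64.1% (95% exact interval 53.5 to 73.9), an odds ratio of 7.82 (5.10 to 11.99, adjusted p = 5.2e-20). The highest signals within 500 bp of their starts were 1239.17 at RpL34b (summit 185 bp upstream, 3R, 9401165 to 9401583), 751.385 at RpS20, 695.154 at RpL32 and 635.4 at RpL14. Each of these 4 summits also lay within 500 bp of the start of another gene (CG8132, CG17271, CG7943 and Nelf-E in this order), so they cannot be assigned to the ribosomal protein genes alone. The replicates differed in this list, with 40 bound genes (43.5%) in replicate 1 and 71 (77.2%) in replicate 3, a mean of 60.3% ± 23.8 (SD, n = 2) and odds ratios of 3.93 and 11.4. Both replicate lists passed the test on their own. Among the 50% of IDR-thresholded peaks with the stronger signal, 18 of 92 ribosomal protein genes were bound, and the odds ratio of 1.99 no longer passed (adjusted Fisher p = 0.0502). With a window of 200 bp the odds ratio rose to 13.09. A summit at RpS20 was within 500 bp of the start in replicate 3 and not in replicate 1.

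The Notch pathway, which acts in cell fate choice between neighbouring cells, had 12 of 21 genes bound, 57.1% (95% exact interval 34.0 to 78.2), an odds ratio of 5.76 (2.43 to 13.7, adjusted p = 3.7e-04), with 12 and 13 in the replicates. With a window of 200 bp the odds ratio of the Notch list was 3.75 (adjusted Fisher p = 0.0190). Its highest signals were at E(spl)mdelta-HLH (3510.85, summit 333 bp upstream, 3R, 25996936 to 25997540), numb (2679.55), E(spl)m3-HLH (2613.12) and E(spl)m7-HLH (2446.64). The ecdysone response list, named after the steroid hormone that drives metamorphosis, had 18 of 36 genes bound, 50%, an odds ratio of 4.33 (2.25 to 8.32, adjusted Fisher p = 1.0e-04), with 15 and 19 in the replicates. Its highest signals were at the transporter gene E23 (4307.93, summit 263 bp upstream, 2L, 3354810 to 3355384), the nuclear receptor gene Eip75B (1952.27), Ldh, which is in the glycolysis list too, and Eip93F (1124.3). These genes have 2.47 starts on average against 1.32 over all genes, and within strata of the number of starts the odds ratio of the ecdysone list was 2.15 (Mantel-Haenszel chi-square, adjusted p = 0.0788).

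The Hippo pathway, which restrains tissue growth, had 8 of 16 genes bound, an odds ratio of 4.32 (1.62 to 11.5, adjusted Fisher p = 0.0152), with ft (2622.66), app (1687.6), Mer (1058.8) and yki (862.732) highest. The replicates gave 7 and 11 bound genes of the Hippo list, with odds ratios of 3.94 and 7.35. The call of the Hippo list ended among the stronger 50% of peaks (odds ratio 3.71, adjusted Fisher p = 0.0605) and with a window of 200 bp (adjusted p = 0.176).

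The other 5 lists with more bound genes passed in replicate 3 and not in replicate 1. Polycomb and Trithorax group proteins, which keep genes silent or active through development, had 12 of 29 genes bound (odds ratio 3.05, 1.45 to 6.39, adjusted Fisher p = 0.0179), with 7 in replicate 1 (odds ratio 1.61, adjusted p = 0.454) and 22 in replicate 3 (odds ratio 10.5, adjusted p = 1.5e-08). Their highest signals were at ph-p (5492.56), brm (3250.42), E(z) (2455.65) and jing (1042.14). Autophagy genes were bound in 9 of 20 cases (odds ratio 3.53, adjusted Fisher p = 0.0179), with 6 in replicate 1 (odds ratio 2.17, adjusted p = 0.219) and 13 in replicate 3 (odds ratio 6.21), and Atg2 (2031.88), Atg17 (1417.46), Atg4b (998.937) and Atg18a (901.735) were highest, each with the start of another gene within 500 bp of its summit (CG12093, Xe7, Hibch and ERR).

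Mitochondrial ribosomal proteins were bound in 23 of 73 cases (odds ratio 1.99, adjusted Fisher p = 0.0246), with 18 in replicate 1 (adjusted p = 0.164) and 33 in replicate 3. The strongest of them were mRpL41 (7697.9), mRpS10 (6881.25, the same summit as for its neighbour Art3), mRpS23 (6172.85) and mRpL23 (4394). Translation factors were bound in 17 of 53 cases (odds ratio 2.04, adjusted Fisher p = 0.0459), with 12 in replicate 1 (adjusted p = 0.401) and 22 in replicate 3, and the strongest were eIF4EHP (6364.25, the same summit as for its neighbour CG18428), eIF6 (3517.52), eIF5B (1035.98) and eIF3h (995.868). The Wnt pathway had 10 of 27 genes bound (odds ratio 2.54, adjusted Fisher p = 0.0496), with 8 in replicate 1 (adjusted p = 0.158) and 13 in replicate 3, and sgg (3413.41), nkd (1195.03), fz3 (661.804) and Apc2 (459.863) were highest. Set against protein-coding genes alone, all 5 lists missed the threshold, with adjusted p between 0.0699 for Polycomb and Trithorax group proteins and 0.157 for translation factors. Among the stronger 50% of peaks 4 of the 5 missed it, autophagy being the exception, with a highest adjusted p of 0.687 for the Wnt pathway. Polycomb and Trithorax group proteins, translation factors and the Wnt pathway missed it with a window of 1000 bp, and the translation factors and the Wnt pathway also within strata of the number of starts (Mantel-Haenszel chi-square, adjusted p = 0.127 and 0.243) and by permutation in circular shifts of the bound calls along the genes (adjusted p = 0.0602 and 0.0895).

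**Figure D3:**
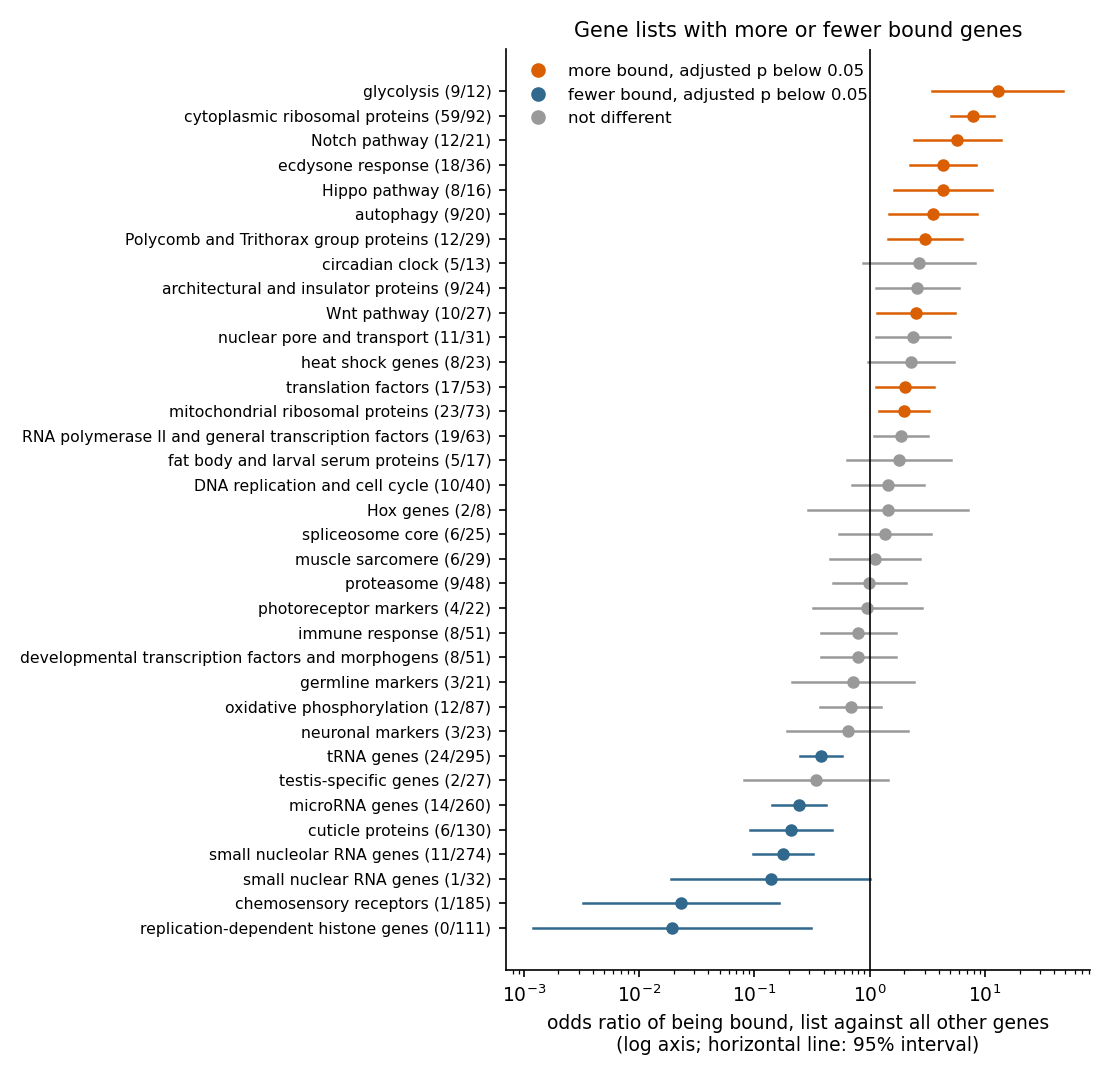
Odds ratio of being bound (log axis) for 35 gene lists against all other genes, with 95% intervals as horizontal lines and bound over all genes of each list in brackets. The 10 lists in orange lie above 1 and the 7 in blue below it, from glycolysis with 9 of 12 bound to histone genes with 0 of 111, drawn with a correction of the zero count.

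The lists with fewer bound genes were those of chemosensory receptors, cuticle proteins, histones and 4 classes of small RNA genes. The chromatin came from whole pupae, so a site bound in few cells may not reach a peak. This limit was not tested, and it holds here and for the tissue markers below. Of 185 chemosensory receptor genes, which serve smell and taste, only Gr77a was bound (signal 423.935, summit 133 bp upstream, 3L, 20739436 to 20739659), 0.541% (95% exact interval 0.0137 to 2.97), an odds ratio of 0.0231 (adjusted p = 1.7e-14). Of 130 cuticle protein genes 6 were bound, 4.62% (odds ratio 0.207, 0.0912 to 0.470, adjusted Fisher p = 1.4e-05), with 7 and 6 in the replicates, among them the chitinase genes Cht7 (1756.95) and Cht11 (889.039) and the structural gene Cpr72Ea (604.733). No replication-dependent histone gene out of 111 was bound in the IDR-thresholded list or in either replicate (adjusted Fisher p = 1.2e-09). Counted as independent genes, this allows a share of up to 2.70%. By permutation in circular shifts of the bound calls along the genes, which keep neighbouring genes together, the adjusted p was 0.0303.

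Small nucleolar RNA genes, which guide chemical changes of ribosomal RNA, were bound in 11 of 274 cases, 4.01% (odds ratio 0.178, 0.0970 to 0.325, adjusted Fisher p = 4.5e-12), with 8 and 19 in the replicates. The odds ratio of this list was 0.245 in replicate 3 and 0.150 in replicate 1, and its highest signals were at snoRNA:Psi28S-2949 (609.408), snoRNA:Me18S-C1096 (446.317) and snoRNA:Or-CD11a (413.717). These 3 summits lay within 500 bp of starts of other genes too, Uhg4 for the first, CG6693 and RpL3 for the second and RpL28 and eIF1 for the third, so they cannot be assigned to the small nucleolar RNA genes alone. Over all called lists 29 of the 53 summits named for a gene had a start of another annotated gene entry within 500 bp, and the same limit holds for them. For the microRNA genes named below, these other entries carry transcript identifiers, and they may not be separate genes. MicroRNA genes were bound in 14 of 260 cases (odds ratio 0.242, 0.141 to 0.415, adjusted Fisher p = 2.6e-09), with 14 and 16 in the replicates, and mir-9377 (1550.24), mir-2491 (1216.23) and mir-ban (526.433), the growth-promoting bantam, were highest. Transfer RNA genes, often enriched without a specific interaction in ChIP, were bound in 24 of 295 cases, 8.14% (odds ratio 0.377, 0.248 to 0.573, adjusted Fisher p = 2.1e-06), with 17 and 33 in the replicates, and tRNA:Tyr-GTA-1-8 (3204.5), tRNA:Gln-TTG-2-1 (1766.88) and tRNA:Lys-TTT-1-1 (1095.33) were highest. Among 32 small nuclear RNA genes only snRNA:7SKa was bound (326.65, adjusted Fisher p = 0.0459), and the interval of the odds ratio of 0.139 ran from 0.0189 to 1.02. This call was lost in each replicate list (odds ratio 0.476, adjusted Fisher p = 0.264 in replicate 3, and 0.163, adjusted p = 0.121 in replicate 1) and in 7 of 9 alternatives. The odds ratios of some of these lists moved with the promoter window and stayed below 1. At 200 and 1000 bp they were 0.0541 and 0.683 for small nucleolar RNA genes, 0.232 and 0.608 for transfer RNA genes, 0.116 and 0.319 for cuticle proteins and 0.0402 and 0.0513 for chemosensory receptors, and at 1000 bp 0.392 for microRNA genes. Histone and transfer RNA genes have near-identical copies, and the treatment of reads that match several places is not given in the sources used here. For microRNA and small nucleolar RNA genes the starts used were those of short annotated entries, such as 642208 to 642288 for mir-ban. Whether a longer transcript that holds such an entry starts elsewhere was not examined. The low counts of these lists therefore concern the entries and say little about binding at such starts.

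The remaining 18 lists were not called, with adjusted p from 0.0599 to 1. Closest to the threshold were architectural and insulator proteins (9 of 24 bound, odds ratio 2.59), RNA polymerase II and general transcription factors (19 of 63, 1.87) and nuclear pore and transport genes (11 of 31, 2.37). In replicate 3 alone the first and the second of these passed (adjusted Fisher p = 0.0249 and 2.2e-04), and in replicate 1 alone they did not (0.195 and 0.112). RNA polymerase II and general transcription factors passed within strata of the number of starts too (odds ratio 2.34, 1.34 to 4.06, Mantel-Haenszel chi-square, adjusted p = 0.00734). With a window of 200 bp all 3 lists passed (adjusted Fisher p = 0.0365 for architectural and insulator proteins, 0.00393 for RNA polymerase II and general transcription factors and 0.0470 for nuclear pore and transport), and among the stronger 50% of peaks the first did (odds ratio 3.36, adjusted p = 0.0380). The heat shock genes had 8 of 23 bound (adjusted Fisher p = 0.102) and in replicate 3 alone 10 of 23 (adjusted p = 0.0463). Other housekeeping lists lay near the share of other genes, with 9 of 48 proteasome genes, 12 of 87 oxidative phosphorylation genes, 6 of 25 spliceosome core genes and 10 of 40 genes of DNA replication and the cell cycle bound. The proteasome and oxidative phosphorylation lists count paralogs of their subunits too, such as Prosbeta2R1 and COX4L, both unbound. Their shares are therefore not those of the main subunits alone. The developmental lists had 2 of 8 Hox genes and 8 of 51 developmental transcription factors and morphogens bound. Among tissue markers, bound genes numbered 6 of 29 for muscle sarcomere, 3 of 23 for neurons, 4 of 22 for photoreceptors, 5 of 17 for fat body and larval serum proteins, 3 of 21 for germline and 2 of 27 for testis. The circadian clock had 5 of 13 and the immune response 8 of 51. In replicate 3 alone testis-specific genes, with 1 of 27 bound, passed as fewer (adjusted Fisher p = 0.0220).

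The same gene could be bound in 1 replicate and not in the other, and 7 lists showed this unevenly between the replicates (exact McNemar test, adjusted p below 0.05). All 7 had more genes in replicate 3. For cytoplasmic ribosomal proteins 33 genes were bound in replicate 3 alone and 2 in replicate 1 alone (exact McNemar test, adjusted p = 1.3e-06), and for Polycomb and Trithorax group proteins 15 and 0 (adjusted p = 0.00107). Transfer RNA genes (18 and 2), mitochondrial ribosomal proteins (17 and 2), RNA polymerase II and general transcription factors (14 and 2), translation factors (10 and 0) and proteasome genes (9 and 0) followed, with adjusted p from 0.00470 to 0.0209. Over all genes the numbers were 1509 and 316, so an excess in replicate 3 was general. In Fisher exact tests against this split among the other genes, an alternative chosen after seeing the data, none of the 35 lists passed, with adjusted Fisher p = 0.501 for cytoplasmic ribosomal proteins, 0.519 for Polycomb and Trithorax group proteins and 1 for the other 5. These tests compare the 2 libraries and not conditions.

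The DNA at the summits was rich in A and T. Windows reaching 50 bp to each side of the 9657 IDR-thresholded summits held 31.7% G and C (SD 9.11 across windows), against 42.5% (SD 10.7) in control windows at the same distance from starts of genes without a peak. The windows of replicates 1 and 3 held 30.9% and 33.5%, a mean of 32.2% ± 1.85 (SD, n = 2). From 200 to 400 bp away from the IDR-thresholded summits the content was 45.4%, so that it dropped by 13.8 percentage points toward the summit. In 5 equal groups by signal the content was 28.5% in the strongest and 34.8% in the weakest group, and across peaks the Spearman correlation of GC content with signal was −0.242, with −0.201 and −0.311 in the replicates. Intergenic summits had 29.6%, intron summits 31.2% and promoter summits 33.6%.

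**Figure D4:**
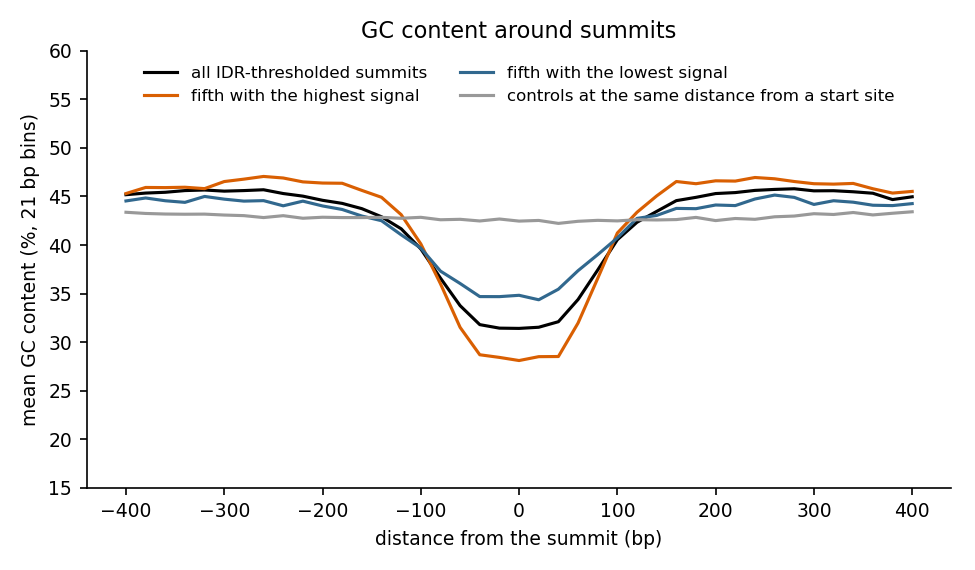
Mean GC content in percent (lines, with an axis that starts at 15) by distance in bp from the summit. Lines show all IDR-thresholded summits, the strongest and the weakest of 5 equal groups by signal, and the distance-matched control windows. At the summit the content is 31.4% for all peaks, 28.1% for the strongest and 34.8% for the weakest group, against 42.5% in the distance-matched controls.

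Of 22 known motifs, 5 were more frequent at summits than in distance-matched controls and 7 were less frequent (two-sided Fisher exact test, adjusted p below 0.05 over the 22). The TATA box was found in 11.1% of windows against 5.08% (odds ratio 2.34, 2.09 to 2.61, adjusted Fisher p = 5.8e-53), Motif 6, a core promoter element, in 4.76% against 2.53% (odds ratio 1.93), and the GATA motif in 24.4% against 17.4% (odds ratio 1.53, 1.43 to 1.64, adjusted p = 4.9e-32). The core of Su(Hw), an insulator protein, had an odds ratio of 1.72 (adjusted Fisher p = 0.0197), which did not pass among the stronger 50% of peaks (1.48, adjusted p = 0.269). The heat shock element rested on 20 summit windows and 7 control windows (odds ratio 2.86, adjusted Fisher p = 0.0350), and with another random draw of controls for the same peaks it was 1.54 (adjusted p = 0.407), with 1.08 in replicate 3 and 2.57 in replicate 1, neither called. The E-boxes CACGTG (odds ratio 0.333, adjusted Fisher p = 1.9e-10) and CAGCTG (0.453, adjusted p = 1.7e-20), the CTCF core (0.493), the Zelda motif (0.482), the BEAF-32 core CGATA (0.787), the Pho motif (0.714) and Motif 7 (0.769) were less frequent. Motif 7 did not pass in replicate 3 alone (0.913, adjusted Fisher p = 0.355), nor Pho in replicate 1 alone (0.823, adjusted p = 0.0861). With flanking windows as controls the BEAF-32 core (0.973, adjusted Fisher p = 0.669), Motif 7 (0.969, adjusted p = 0.793), Zelda (0.651, adjusted p = 0.142) and the heat shock element (2.22, adjusted p = 0.112) were not called. Against the same flanking windows Motif 1 (2.91, adjusted Fisher p = 0.00818) and DRE (2.05, adjusted p = 0.0177) were more frequent and the Scalloped motif (0.753, adjusted p = 0.0376) less frequent, none of which was called for the full list against distance-matched controls. DRE was less frequent among the stronger 50% of peaks (0.406, adjusted Fisher p = 0.0273). Called less frequent under single alternatives were also the Initiator in replicate 3 alone (0.876, adjusted Fisher p = 0.0119) and in windows of 100 bp to each side (0.869, adjusted p = 3.4e-04), the nuclear receptor motif AAGGTCA in the latter (0.654, adjusted p = 3.3e-04) and the tRNA B box with another random draw of controls (0.0588, adjusted p = 0.0151).

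Another set of control windows, chosen after seeing the data, was matched to the summits in GC content. These windows were drawn from anywhere on the arms and not matched in distance to a start, with 13.04% at promoters against 30.5% of summits, so the changes below cannot be put down to GC content alone. Most of the differences above were not called against them. The TATA box had an odds ratio of 1.02 (0.929 to 1.11, adjusted Fisher p = 0.914) and Motif 6 of 1.08 (adjusted p = 0.513), and no motif was called less frequent. GATA stayed more frequent at 1.12 (1.05 to 1.202, adjusted Fisher p = 0.00326), and Motif 7 turned to 1.41 (adjusted p = 0.00326). Against these controls the GAGA motif was found in 150 summit windows and 55 control windows (odds ratio 2.75, 2.02 to 3.76, adjusted Fisher p = 4.0e-10), and Motif 1, which M1BP binds, in 29 and 6 (odds ratio 4.84, 2.01 to 11.7, adjusted p = 0.00127). Against distance-matched controls GAGA had an odds ratio of 1.30 (adjusted Fisher p = 0.0651) and Motif 1 of 1.16 (adjusted p = 0.751). The value for GAGA was not stable, with 1.41 in another random draw of controls for the same peaks (adjusted Fisher p = 0.0151), 1.05 in replicate 1, 2.14 in replicate 3 (adjusted p = 2.9e-11), 0.448 among the stronger 50% of peaks (adjusted p = 0.00101), 1.87 in windows of 100 bp to each side (adjusted p = 3.2e-12) and 0.840 against flanking windows (adjusted p = 0.182).

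Words of 8 bases were ranked on 2L, 3L and X and the top 10 were tested on 2R, 3R and 4. All 10 were made of A and T alone and passed on the other arms (two-sided Fisher exact test, adjusted over the 10), with odds ratios from 1.98 for AAATTAAA to 3.26 for TTAAAAAA. Summit windows held 31.7% G and C and the distance-matched controls 42.5%, which by itself favours words of A and T. The test on the other arms therefore cannot tell a specific word from this difference. AAAAAAAA was in 8.88% of the tested summit windows and in 3.91% of controls (adjusted Fisher p = 5.4e-20). With GC-matched controls, which were not matched in distance to a start, 6 of 10 words passed, of which 5 were enriched and none of these was made of A and T alone. The other, AAAAATTT, was less frequent at summits (odds ratio 0.734, adjusted Fisher p = 0.0275). The enriched words were led by CACTGAGA, in 33 of 3807 summit windows and 5 of 4018 controls (odds ratio 7.02, adjusted Fisher p = 1.6e-05), and TCAGTGCA, in 31 and 11 (odds ratio 2.99, adjusted p = 0.00519).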

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

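The shares in this part were computed only after the number of these peaks was seen. The pooled list held 2308 peaks with the highest −log10 q of the list that were left out of the IDR-thresholded list, a signal in deposited data that no comparison of the report used. Their signals reached 170.1, just under the lowest signal of the IDR-thresholded list (170.2), with a median of 146.4. A replicate 1 peak overlapped 93.9% of them and a replicate 3 peak 94.3%, and 242 overlapped an IDR-thresholded peak. They lay at promoters in 29.2% of cases, in introns in 43.9%, between genes in 23.8% and in coding exons in 0.390%, against 30.5%, 45.3%, 21.6% and 0.186% of the thresholded peaks. The X chromosome held 22.2% of them and 19.2% of the thresholded peaks. Their windows had a GC content of 35.6% (SD 10.4), somewhat above that of the weakest of the 5 groups of thresholded peaks (34.8%). Because the thresholded list is the strongest 9657 pooled peaks, the boundary between used and unused peaks is a signal value, and no biological explanation was tested.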

How the results depend on the processing

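Tests against GC-matched controls, of the replicates against the split among other genes, with 1 summit per merged region and within strata of the number of starts were chosen only after the results were seen, and the cause of each change below was not tested unless stated. Of the values that answer a comparison, 75 stayed within their spread, or within 1.5 times for counts, under an alternative and 35 moved. Taking the strongest pooled peaks moved none of these values apart from the random draw of controls, since these are the same peaks. The 75 include these unchanged values. They also include values from the lists of single replicates, where a promoter share of 38.2% in replicate 3 against 30.5% counted as staying. The number is therefore not a measure of stability. Requiring an overlap of 50% of both peaks gave 67.4% of replicate 1 and 68.8% of replicate 3 peaks as shared, summits within 100 bp gave 75.3% in both directions, all peaks gave 71.5% and 75.5%, and the top 1000 gave 90.4% and 90.3%. The correlation between replicates was 0.910 in the stronger 50% of peaks, 0.865 with summits within 100 bp and 0.902 by Pearson on log2 signal. Windows of 200 and 1000 bp change, by construction, the shares of promoters (18.7% and 40.9%), introns (50.6% and 38.8%) and coding exons (0.228% and 0.0932%). The window of 200 bp gave 26.4% for intergenic sequence and 2142 bound genes, and protein-coding genes alone gave 25.6% for intergenic sequence. The stronger 50% of peaks gave 0.0414% in coding exons, 1986 bound genes (fewer peaks by construction) and a ratio of 1.06 for X. For the full IDR-thresholded list the ratio for X was 1.17 against the share of starts. Across the lists without replicate 1 or without replicate 3, coding exons held 0.135% to 0.186%, the ratio was 1.08 to 1.09 for X and 0.103 to 0.247 for chromosome 4, and 5 to 13 lists had more bound genes. With the stronger 50% of peaks, and with protein-coding genes alone, 5 lists had more bound genes, and with the latter 3 had fewer, since that background leaves out the noncoding lists. For single lists, 134 results kept their call and 32 lost it, none reversing. The 134 include the strongest pooled peaks, which could change no list call as they are the same peaks. Glycolysis, Notch, histone, transfer RNA, small nucleolar RNA, microRNA, cuticle and chemosensory genes kept theirs under every alternative run for them, with highest adjusted p values of 0.0297, 0.0190, 0.0303, 0.0127, 0.0413, 7.8e-04, 0.00181 and 7.8e-04. The p of the circular shifts went down to 2.0e-04, the smallest that 10000 shifts can give. For single motifs 71 results kept their call, 22 lost it and kept their direction, and 3 changed direction. These 3 were all against GC-matched controls: Motif 7 (1.41, adjusted Fisher p = 0.00326), Zelda (1.67, adjusted p = 0.348) and the CTCF core (1.12, adjusted p = 0.751). Only Motif 7 was called in the other direction, whereas Zelda and the CTCF core lost their call. With these controls 0 motifs were less frequent, and 6 words passed in place of 10, of which 5 were enriched where all 10 had been, but they differ from the distance-matched ones in position as well as in GC content. Among the stronger 50% of peaks 3 motifs were more frequent. Of the 7 lists bound unevenly between the replicates, 0 were called against the split among the other genes. The self-test made calls at these numbers of genes, and depth limits what cannot be seen here, since the lists give no read counts. No analysis paired across conditions was possible because there is only 1 group.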

Other observations

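The tests on other housekeeping genes and on counting divergent pairs, and the genes named in the next sentences for their many summits, were chosen only after the results were seen. Several long genes carried many bound sites inside the gene. kirre, a cell adhesion gene of muscle founder cells (X, 2740384 to 3134532), held 44 IDR-thresholded summits, Tet, the fly relative of the TET dioxygenases, held 29, Snoo 27, and CG43658 and sbb 26 each. Per 10 kb this made 1.12 summits in kirre, 3.12 in Tet, 2.90 in Snoo and 3.29 in sbb, against 0.721 over the arms. The numbers in the lists of replicates 1 and 3 were 49 and 37 for kirre, 26 and 29 for Tet and 24 and 23 for sbb. In all, 34 genes held 15 or more summits.

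The densest of these 34 genes were Mnt, a relative of the Myc antagonists, with 16 summits and 5.36 per 10 kb, tara with 15 and 4.33, the cell cycle regulator E2f1 with 16 and 3.94, the zinc finger gene shn with 22 and 3.77, and brat, a translational repressor that limits growth of neural stem cells, with 16 and 3.48. Others of the 34 were the GATA cofactor ush, which held 21, the homeobox gene hth with 21, the Notch coactivator mam with 18, the Wnt receptors fz and fz2 with 21 and 17, and Eip75B with 17. No test was run on these counts, since long genes hold more sites by their length.

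The design gives 1 group, so the explanations that follow were set against the annotation and the sequence alone and not against a second condition.

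The low GC content of the summits and their near absence from coding exons might come from base composition alone, by a bias of the libraries or the caller toward A/T-rich DNA. Against that as the whole cause, low-GC windows held a summit 2.51 times as often in promoters as in intergenic sequence (95% interval 2.30 to 2.73), with shares of 4.52% and 1.80%. Windows matched in GC content and without a peak lay in coding exons in 3.81% of cases (3.44 to 4.21), well above the 0.186% of summits. Soft-masked sequence held 25.4% of summits (24.5 to 26.3) and 35.5% of GC-matched windows, so repeats were not in excess at the summits. A part played by repeats is not excluded by this, since these windows were not matched in position. The treatment of reads that match several places is not known either. What stays open is a partial bias, or one that acts on open chromatin, which no value here tests. The low-GC windows of promoters and of intergenic sequence were not matched in repeats or in how low their GC content lay. The ratio of 2.51 may therefore partly reflect such differences.

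Ribosomal protein promoters could be bound often because their sequence is poor in GC, as 32.8% of genes in the decile with the lowest GC content near the start were bound and 8.65% in the highest. Within these deciles the Mantel-Haenszel odds ratio was 6.55 (95% interval 4.25 to 10.1), against 7.82 without them, so base composition was not the whole cause. A general excess at highly expressed housekeeping genes and one at this list cannot be told apart. Oxidative phosphorylation and proteasome genes together had 21 of 135 genes bound, an odds ratio of 0.792 (0.497 to 1.26). However, their counts had been seen when they were picked. Both lists also hold paralogs of their subunits, such as Prosalpha6T, Rpt3R, COX4L and ATPsynbetaL, none of these bound. Whether such paralogs are highly expressed was not measured, so the value depends on the make-up of the lists. Other housekeeping lists lay higher, with 12.96 for glycolysis and 2.04 for translation factors. Open too are differences in expression, which was not measured here, and the strength of the sites, since the median signal at bound ribosomal protein genes was 344.1 against 453.6 for all bound genes. It remains a hypothesis that was found and tested on the same peaks.

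Promoters took 38.2% of the replicate 3 list and 26.6% of the replicate 1 list. Among the 1000 strongest peaks of each list the shares were 42.1% and 42.0%, a difference of 0.100 percentage points (95% interval −4.23 to 4.43). A difference that lies among the weaker peaks would give this. However, 90.4% and 90.3% of these peaks overlapped between the lists, which by itself makes their shares alike. The interval treats the lists as independent, so the test is weak on its own. Among the strongest 3000 the difference was 3.10 points (0.692 to 5.51), and among all 30000 it was 9.70. Whether the weaker replicate 3 peaks at promoters are noise or real sites cannot be read from the lists, as no depth is given.

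Bound genes may more often share their promoter region with a gene on the other strand. Among protein-coding genes, 45.9% of bound and 22.3% of unbound genes had a start on the other strand within 500 bp facing away, an odds ratio of 2.95 (95% interval 2.71 to 3.22), but a summit near such a pair counts for both genes, which fixes part of this excess. The control for this was changed after its result was seen, and all versions are given. Promoter summits lay within 500 bp of both starts of such a pair in 24.7% of cases, against 8.88% of random promoter positions (odds ratio 3.37, 3.04 to 3.73), 20.5% of positions at the same distance from starts of any genes (1.27, 1.17 to 1.39) and 23.6% of positions at the same distance from starts of genes of the same kind (1.06, 0.974 to 1.16, Fisher exact p = 0.173). With the closest control the excess is in line with double counting alone, and the gene-level preference and the counting cannot be told apart.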
